A study of Oryza sativa Japonica Group with 2 samples.

How the data were processed

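Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on rice (Oryza sativa Japonica Group) endosperm, the starch-storing tissue of the grain, harvested 7 days after pollination. The series holds 2 libraries, 1 per group. One was precipitated with an antibody against the FLAG epitope from plants that carry a FLAG-tagged NF-YC11, and the other is the input chromatin without precipitation. NF-YC proteins are one of the subunit families of NF-Y, the heterotrimeric transcription factor that recognises the CCAAT box. Per the labels' protocols, 3 g of tissue per sample was crosslinked in 1% formaldehyde for 30 min and the chromatin was sonicated to 200 to 500 bp.

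BWA and MACS2 were used, per the submitters' processing notes; their versions, the genome build, the mapping filters and the treatment of duplicate reads are not given in the sources used here. The authors deposited 1 table of peaks and 1 list of summits for the ChIP library against the input. Both name the chromosomes 1 to 12 and carry unplaced contigs whose names begin with Syng_TIGR. The deposited pileup is a signal, the number of ChIP fragments that cover the summit, and it is a whole number throughout. The deposited fold enrichment is the ratio of ChIP to local input background, per the file headers. The deposited table also gives the −log10 of a p-value and the −log10 of a q-value per summit; both header cells were damaged by a spreadsheet and were identified from their order and values. All 4445 summits of the table were found in the summit list at the same position, with −log10 q values that differed by 0. Peaks were called on 1 ChIP and 1 input library, so there is no replicate check, and no p-value here compares tagged endosperm with untagged endosperm.

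Background was recovered from the deposited values by taking the fold enrichment as (pileup + 1) / (background + 1). A Poisson upper tail of the pileup at that background gave the deposited −log10 p of every summit to within 0.00032. Of the recovered backgrounds, 99.9% were whole multiples of 0.745 ChIP-scaled fragments in a window of 149 bp, 1000 bp or 10000 bp, or equalled the lowest value of 4.85, with tolerances of 0.001, 0.0005 and 0.0005. One input fragment therefore counted as 0.745 in the comparison, which corresponds to an input library 1.34 times as large as the ChIP library. The narrowest region measured 149 bp, which was taken as the fragment length. The total read number of each library is unknown; the lowest background of 4.85 fragments, if it is the genome-wide rate, corresponds to 0.0326 ChIP tags per bp of the genome size that was set. The lowest −log10 q in the table was 1.31, a q of 0.0491, so the list ends at a q of 0.05. At the lowest background the smallest pileup called was 14 fragments, a fold enrichment of 2.56, and weaker enrichment was not detectable there at this depth.

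Summits that share a region were merged, which left 4193 regions; a region takes the fold enrichment and the background of its highest-fold summit. Summits with a recovered background above 40 ChIP-scaled fragments are called high-background summits; this limit was chosen after the values were seen. They were joined into loci over gaps of up to 50 kb. Intervals on a pileup are exact 95% Poisson intervals, and intervals on a fold treat the background as fixed, so both cover counting error only. Intervals on a median come from binomial order statistics at 95%. They give the uncertainty of the median if summits were independent draws, and summits are not biological replicates. Summits of one locus are not independent, so these intervals can be too narrow. The number of regions per chromosome was tested one-sidedly by a chi-square statistic against the span from the first to the last region of each chromosome, with 100000 multinomial draws. These draws treat regions as independent of each other. The spacing of regions was tested two-sidedly with 1000 placements of each region at random within its chromosome's span. The p-values are called permutation p here, although no observed positions were reshuffled. They were Benjamini-Hochberg adjusted over the 12 tests of this kind. Assembly gaps and unmappable sequence were not masked in these placements and were not taken out of the spans. Placed regions could overlap and then counted as neighbours, whereas called regions lay at least 0.141 kb apart. This raises the random share of neighbours by an amount that was not measured. The smallest p these tests can give is 1e-05 for the chromosomes and 0.002 for the placements. The 3 placement measures were added after the files were seen, as was the comparison of the counts per 1 Mb window with 1000 such placements, for which no p is given.

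On simulated lists of 4188 regions, the neighbour test called 4 of 100 unclustered lists and 100 of 100 lists with planted neighbours at p up to 0.05. The outer-share test called 7 of 100 unclustered lists. The chromosome test called 6 of 100 even lists and 100 of 100 lists in which 1 chromosome had 1.5 times the density. The unclustered and even lists were drawn in the same way as the tests' own random draws, so their low call rates were built in. These rates say nothing about lists like the observed one, whose regions are clumped and do not overlap. The planted neighbours and the planted density were stronger than the excesses found over all regions (1.23 times at most for a chromosome). These simulations used fewer random draws than the tests and did not cover the smaller sets of regions. They do not show how small an effect the tests can detect. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

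The tests of peak number, fold and chromosomes, the rule for named regions and the stricter thresholds of 5 on −log10 q and fold were fixed before the data were examined, as was the use of the 12 chromosomes alone. Planned tests of promoters, the CCAAT box, the GCC box, other motifs, 6-mers and gene lists need a genome or annotation that fits the files' coordinates. The gene table at hand belongs to assembly ASM3414082v1 and no build is named for the files, so those tests were not run and regions are given by position alone, without gene names. Chromosome lengths were planned for the chromosome test and were replaced by the spans. Named regions are the 12 with the highest fold enrichment on the chromosomes, the rule set for the case without annotation. Loci of at least 5-fold and high-background loci are described in addition and were chosen after their values were seen. Alternatives were stricter thresholds on −log10 q (5) and fold enrichment (5), the 12 chromosomes alone and, chosen after the data were seen, a q of at most 0.01, the removal of high-background summits, other limits on background (20 and 100) and summits as the unit.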

Results

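Binding of FLAG-tagged NF-YC11 was mapped in rice endosperm at 7 days after pollination by comparing 1 ChIP library with 1 input library. The question was where in the genome this NF-Y subunit binds in the developing endosperm. The authors' peak list held 4193 regions with 4445 summits, of which 4440 summits lay on the 12 chromosomes and 5 on 2 unplaced contigs. The regions covered 904 kb together, with a median width of 191 bp and quartiles of 162 and 242 bp. A single summit was reported in most regions, and 223 regions (5.32%) held several, up to 6. Positions are given in the coordinates of the deposited files, whose genome build is not given in the sources used here, and annotated genes, exons and UTRs were not analysed here. Each value rests on 1 library per group, so no replicate error can be given.

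The ChIP signal exceeded the input background by a median of 2.70-fold over the 4445 summits (95% interval of the median 2.65 to 2.71, over summits), with quartiles of 2.36 and 3.08. A fold enrichment from 2 to under 3 was found at 2872 summits (64.6%), from 3 to under 4 at 1135 (25.5%), from 4 to under 5 at 125 (2.81%) and of at least 5 at 40 (0.900%). Under 2-fold there were 273 summits, of which 193 had a background above 40 fragments. The median pileup was 24 ChIP fragments, with quartiles of 20 and 30, over a median recovered background of 8.19 ChIP-scaled fragments. A q above 0.01 was listed for 1224 summits (27.5%), which lie closest to the limit of detection.

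**Figure D1:**
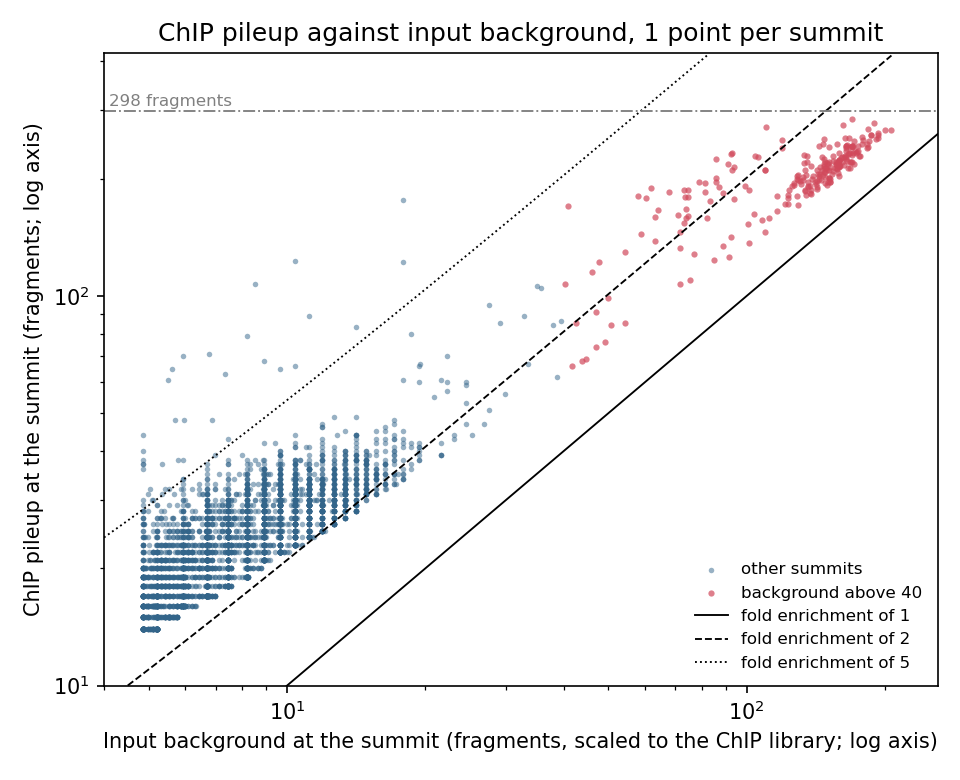
ChIP pileup at each of the 4445 summits (fragments, log axis) against the input background recovered for the same summit (ChIP-scaled fragments, log axis), with lines at fold enrichments of 1, 2 and 5 and a horizontal line at 298 fragments. That background can come from a window of 1000 or 10000 bp or be the lowest value, 4.85. Red points are the 235 summits with a background above 40; none exceeds 285 fragments.

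The strongest enrichment was found at loci on chromosomes 3, 8 and 11. The region at chromosome 3, 28826202 to 28828434, was the widest of the list at 2233 bp and held 5 summits, all at 6.18-fold or more. Its highest summit, at 28826409, had a pileup of 107 fragments (95% Poisson interval 87.7 to 129) over a background of 8.54, an 11.3-fold enrichment (9.29 to 13.7). On chromosome 8, 3 neighbouring regions between 2079031 and 2081204 reached 10.9-fold (9.03 to 12.9), 9.95-fold (7.71 to 12.6) and 5.74-fold. On chromosome 11, the region at 18303020 to 18303645 reached 10.2-fold (7.99 to 12.9), and its neighbour at 18301304 to 18302866 reached 9.50-fold (7.30 to 12.2) with 4 summits, the lowest at 2.39-fold. At lower coordinates than this pair, 6 further summits from 18288976 to 18296428 had folds of 4.41 to 4.83. Within 20 kb of the loci on chromosomes 3 and 8, 0 further summits reached 4-fold. The intervals on the folds that are given here overlap one another, so the order of those summits cannot be told from counting error. These summits were picked for their high fold, which the intervals do not allow for.

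Other strong regions lay on chromosomes 4, 6, 7, 10 and 11. The largest pileup among the 12 strongest, 176 fragments (151 to 204), belonged to chromosome 11, 12123090 to 12123604, at 9.38-fold (8.05 to 10.9) and a −log10 q of 102, the highest in the list. Further along the same chromosome, the region at 12351988 to 12352897 held 4 summits, the highest at 7.69-fold (5.63 to 10.3). The region at chromosome 4, 32336396 to 32337305, had summits at 7.40-fold (5.96 to 9.08) and 5.86-fold. Single-summit regions followed at chromosome 6, 9359477 to 9359733 (7.30-fold, 5.42 to 9.63), and chromosome 7, 14232116 to 14232267 (6.52-fold, 5.42 to 7.77). The last of the 12 were chromosome 6, 16741547 to 16741764, and chromosome 10, 10899153 to 10899327, each with 37 fragments and 6.49-fold (4.62 to 8.88). Both, and the region of chromosome 11 at 12351988 to 12352897, had the lowest background of the list, 4.85. If that is the genome-wide rate, their folds are against this rate and not against a local input count. The 40 summits of at least 5-fold formed 27 loci when summits within 5 kb were joined. Of these loci, 5 held several such summits, 18 in all, and 22 held 1 each.

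Some summits had high signal in both libraries. A background above 40 fragments was found at 235 summits (5.29%), with a median of 143 against 7.45 at the other 4210 summits. Their median ChIP pileup was 209 fragments against 24, while their median fold enrichment was 1.45 (95% interval of the median 1.42 to 1.47) against 2.72 (2.71 to 2.73). The first interval can be too narrow, because 113 of the 235 summits lie in 1 locus and were counted as independent. The fall in fold began below that limit. The median fold was 2.84 at backgrounds up to 10, 2.36 from 10 to 20 and 2.13 from 20 to 40 (28 summits), then 2.21 from 40 to 100 (58 summits) and 1.40 above 100 (177 summits). The lowest fold that was called also fell along these ranges, from 2.09 to 1.85, 1.59, 1.37 and 1.27. Of the 235, 142 were under 1.5-fold, and 0 of the other summits were. The calling threshold admits lower folds as background rises, and no fold under 1.59 was called at backgrounds of 20 to 40. The 0 therefore follows from the threshold, which also contributes to the falling medians by an amount that was not measured. When such summits were joined over gaps of up to 50 kb, the largest locus spanned 220 kb on chromosome 12, from 20459998 to 20679758, and held 113 of these summits in 73 regions that covered 11.8% of it. The next were chromosome 1, 33506291 to 33587477, with 22 summits, chromosome 9, 4679323 to 4731061, with 20, chromosome 12, 8531829 to 8545449, with 9, and chromosome 4, 32873434 to 32929214, with 7. These 5 loci held 171 of the 231 high-background summits on the chromosomes, and their median folds ran from 1.37 on chromosome 4 to 1.48 at the smaller of the loci on chromosome 12.

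Peak density per Mb of span differed between chromosomes. Assembly gaps and unmappable sequence were not taken out of the spans, so a difference in density need not be a difference in binding. Chromosome 3 was the densest, with 503 regions or 13.9 per Mb (95% Poisson interval 12.7 to 15.1), 1.23 times the number its span gives. Chromosome 11 was the sparsest, with 266 regions or 9.23 per Mb (8.16 to 10.4), followed by chromosome 4 with 339 or 9.55 per Mb (8.56 to 10.6) and chromosome 8 with 277 or 9.75 per Mb (8.64 to 11.0). Chromosome 12 had 314 regions, 11.4 per Mb (10.2 to 12.8), of which 86 were high-background regions, and the remaining 228 gave 8.30 per Mb (7.26 to 9.45), the lowest value once these were left out. The counts departed from the spans over all 4188 chromosomal regions (chi-square 60.7 on 11 degrees of freedom, randomised p = 1e-05, the smallest the draws can give) and over the 4023 that remained without high-background regions (chi-square 78.2, p = 1e-05). The draws treat regions as independent, whereas the variance per 1 Mb window was 1.66 times the mean without high-background regions. Such clumping can make these p-values too small, by an amount that was not measured. Among the 618 regions with a −log10 q of at least 5 no departure was found (chi-square 8.95, p = 0.627), nor among the 555 of them that were not high-background regions (chi-square 16.4, p = 0.126). With fewer regions, these tests could miss a difference of the same size. Among the 618, chromosome 11 lay on the other side of its expected number, at 1.17 times with 56 regions (1.14 times without high-background regions). Chromosome 3 lay at 1.04 times with 63. Chromosome 2 was then the densest, at 1.21 times with 72 regions (1.34 times without high-background regions), against 1.05 times over all regions. Chromosome 12 fell from 1.14 times with 52 regions to 0.634 times with 26 when high-background regions were left out of this set.

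**Figure D2:**
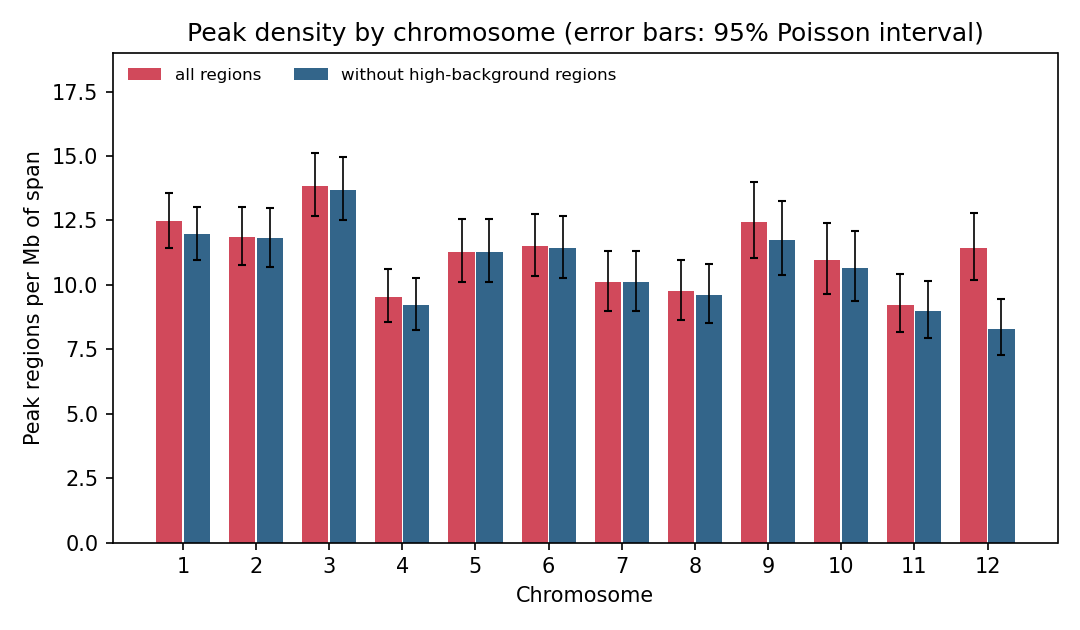
Peak regions per Mb of span (first to last region) for chromosomes 1 to 12, for all regions (red) and without high-background regions (blue); error bars are 95% Poisson intervals and cover counting error only. Chromosome 3 stands highest at 13.9 per Mb, and chromosome 12 falls from 11.4 to 8.30 per Mb without high-background regions.

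Along the chromosomes, regions lay a median of 58.2 kb apart, with quartiles of 21.7 and 123 kb. Without high-background regions, the 366 full windows of 1 Mb held a mean of 10.7 regions and a variance of 1.66 times the mean, above the 1.04 to 1.34 (95% range) of random placement within each chromosome. The densest windows were 10 to 11 Mb and 28 to 29 Mb of chromosome 3, with 25 regions each, and the second of these contains the strongest region of the list. The window from 15 to 16 Mb of chromosome 4 held 0 regions and lies within the longest stretch without a region, 1208 kb from 14797103 to 16004820. The longest stretch under random placement averaged 819 kb (95% range 646 to 1114 kb), and the observed one was longer (permutation p = 0.00999, adjusted p = 0.03). Without high-background regions the same stretch no longer passed the test (permutation p = 0.042, adjusted p = 0.0719). The next longest were 941 kb on chromosome 6, from 17974389 to 18915743, 938 kb on chromosome 4, from 9768661 to 10706170, and 862 kb on chromosome 11, from 12352898 to 13215367.

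Regions were closer together than random placement gives. Another region lay within 5 kb of 14.1% of them, against 11.2% at random (95% range 9.96 to 12.5, permutation p = 0.002, the smallest the placements can give, adjusted p = 0.012). Without high-background regions the share was 11.6% against 10.8% (9.59 to 12.2, permutation p = 0.268, adjusted p = 0.357). No excess of neighbours within 5 kb was thus detected among the others. Placed regions could overlap, which raises the random share, so a small excess could be missed. Regions with a −log10 q of at least 5 had a neighbour of that kind within 5 kb in 7.77% of cases against 1.73% at random (0.639 to 3.24, permutation p = 0.002, adjusted p = 0.012). Without high-background regions that share was 3.60% against 1.60%, which did not pass after correction (permutation p = 0.03, adjusted p = 0.0599). The outer 20% at each end of the spans held 41.7% of all regions against 39.9% at random, which did not pass after correction either (permutation p = 0.028, adjusted p = 0.0599). Without high-background regions they held 42.5%, above the random range of 38.4 to 41.6% (permutation p = 0.004, adjusted p = 0.016). Among regions with a −log10 q of at least 5 the share was 39.2%, under its random mean of 39.9% (permutation p = 0.763, adjusted p = 0.763).

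**Figure D3:**
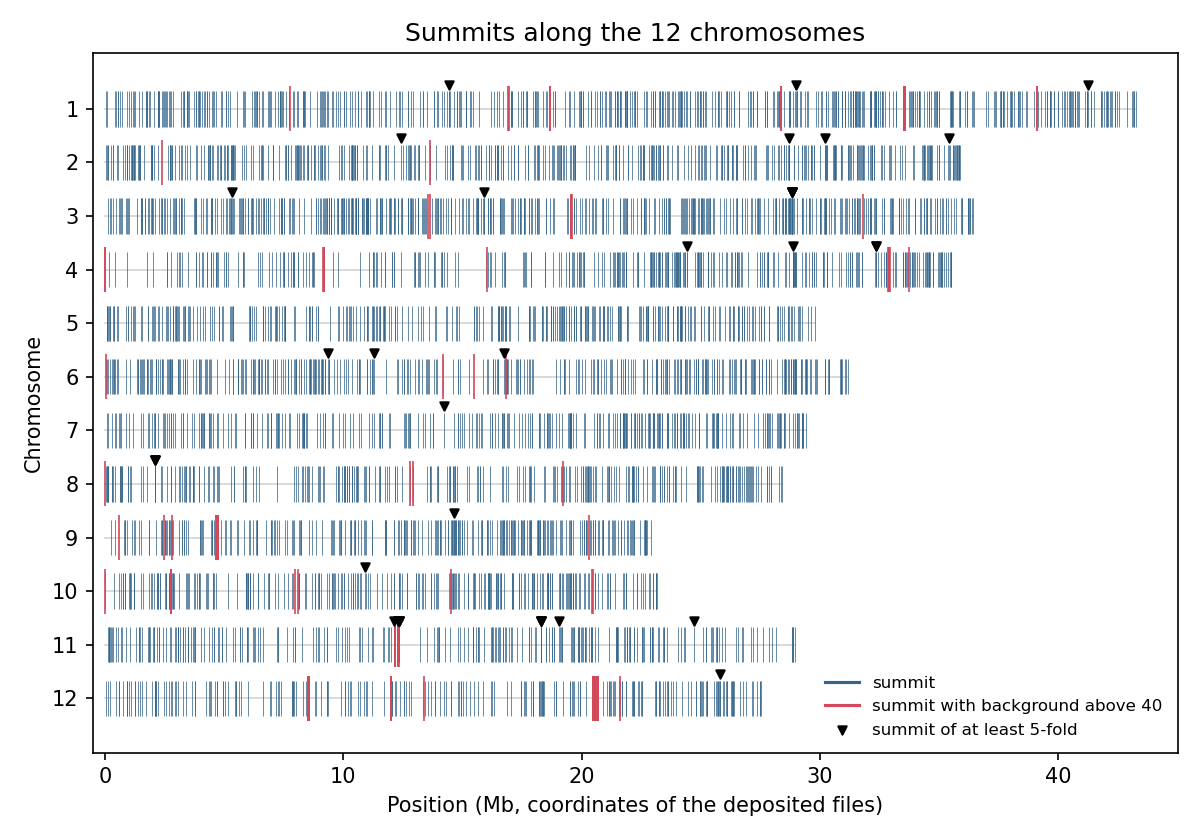
Position of each summit (Mb, coordinates of the deposited files) on chromosomes 1 to 12. Blue ticks are summits, red ticks are high-background summits, and triangles mark the 40 summits of at least 5-fold; the red block at 20.5 to 20.7 Mb of chromosome 12 holds 113 high-background summits.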

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

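The comparisons between chromosomes leave out the unplaced contigs, and 5 summits lay on them. They are listed because they fall outside those comparisons; the number to be expected from the contigs' length was not computed, as their length is not used here. On the contig Syng_TIGR_030, 4 summits lay between positions 87 and 10400, with pileups of 211, 146, 178 and 191 ChIP fragments over backgrounds of 109, 71.5, 60.3 and 99.0. Their fold enrichments were 1.92, 2.03, 2.92 and 1.92. The single summit on Syng_TIGR_035, at 8044, had 34 fragments over a background of 10.3, a fold of 3.09. All 4 summits of Syng_TIGR_030 were high-background summits, and no biological explanation was tested for them.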

How the results depend on the processing

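The alternatives on high background, a q of at most 0.01 and summits as units, and all those on placement, were chosen after seeing the data. Of the 4193 regions, 623 remained at a −log10 q of at least 5 and 30 at a fold of at least 5; 3093 remained at a q of at most 0.01 and 4026 without high-background summits. The median fold of 2.70 became 3.60 at a −log10 q of at least 5, where weak summits are removed by construction, and 2.72 without high-background summits whether the limit on background was 20, 40 or 100 (2.72024, 2.71783 and 2.71768). The chromosomes alone left it at 2.70. The difference between chromosomes kept its call without high-background summits and with summits as units (chi-square 78.2 and 66.7, p = 1e-05 each), and was lost at a −log10 q of at least 5 (8.95, p = 0.627), also without high-background summits, a setting chosen after seeing the data (16.4, p = 0.126), where 618 and 555 regions were tested in place of 4188 and chromosome 11 moved from 0.819 to 1.17 times its expected number. Chromosome 12 then stood at 1.14 times, and at 0.634 times without high-background summits. Chromosome 2 stood at 1.21 times, and at 1.34 times without them. The share with a neighbour within 5 kb, 14.1%, lost its call without high-background summits (11.6%, permutation adjusted p = 0.357) and at a −log10 q of at least 5 without them (3.60%, permutation adjusted p = 0.0599). The longest stretch without a region, 1208 kb, lost its call at the same length without high-background summits (permutation adjusted p = 0.0719), and at a −log10 q of at least 5 it was 4789 kb with and without them (permutation adjusted p = 0.357 and 0.728), where fewer regions leave longer stretches. The share in the outer 20% at each end, 41.7%, passed without high-background summits (42.5%, permutation adjusted p = 0.016), turned to 39.2%, below random, at a −log10 q of at least 5, and was 41.4% with both; the cause was not tested. The alternatives fixed beforehand for promoters, the CCAAT and GCC boxes, the motif panel, 6-mers and gene lists were not run, as no fitting genome or annotation was at hand. No paired analysis was possible because there is 1 library per group, and no replicate could be left out. Depth limits the list at low background, where no fold under 2.56 was called at 4.85 fragments.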

Other observations

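All tests below were chosen after the data were seen; for neighbours among regions of low q, what each outcome would mean was written before its value was known. High-background summits also lay near the start of some chromosomes, in regions that begin at coordinates 1074 to 1130. All 4 chromosomal summits within 2 kb of coordinate 1, on chromosomes 4, 8 and 10, had a background above 40 (44.7 to 92.3), with folds of 1.53 to 2.37. High-background summits were not uniform. The 58 with backgrounds from 40 to 100 had a median fold of 2.21, and 1 of them, on chromosome 10 near 20.5 Mb, reached 4.08. The 177 with backgrounds above 100 had a median fold of 1.40. On chromosome 11, 2 high-background loci, at 12164585 to 12189655 and 12278766 to 12328794, had backgrounds of 63.3 to 93.1, median folds of 2.25 and 2.37, and lie between the strong regions at 12.1 and 12.4 Mb. The span of the second contains a region of 5.55-fold over a background of 14.1, at 12303773 to 12303922.

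The low fold of the 235 high-background summits may be shaped in part by the counting. Pileups never exceeded 285 fragments and unscaled input never exceeded 276, both under 298, the most that fragments of 149 bp can give if 1 read per position and strand is kept; whether duplicates were removed is not given in the sources used here. Capped counts followed by scaling of the 1.34 times larger input could be judged neither at backgrounds from 40 to 100 nor above 100. The calling threshold removes low folds in both ranges. In the lower range there were 1.66 ChIP fragments per unscaled input fragment (95% interval of the median 1.52 to 1.78), but the value under 1 predicted for the cap was out of reach, as no called summit there fell below 1.02. The median fold of 2.21 (2.03 to 2.37) overlapped the 2.13 (1.85 to 2.56) at backgrounds of 20 to 40, which does not show that they are equal. Above 100, the ratio was 1.05 (1.04 to 1.06), and called summits reached down to 0.947. That median met neither the value under 1 predicted for the cap nor the 1.34 or more predicted without it. The ratio is nearly the fold times 0.745, in both ranges, so it holds no information apart from the fold. Weak enrichment without a cap would also give a ratio under 1.34, so the ratio cannot decide between them. The median fold there was 1.40 (1.39 to 1.42). Capped counts and NF-YC11 occupancy cannot be told apart above 100, because the cap limits the fold to 1.97 at the median background. The limit was 4.03 in the lower range (2.99 at its highest background). A correction for the cap raised the median fold from 2.21 to 2.72 in the lower range and from 2.13 to 2.29 at backgrounds of 20 to 40. The median fold rose from 1.40 to 1.47 above 100, and from 1.45 to 1.55 over the 235. The correction assumes that fragments fill the positions evenly, which was not checked, so it excludes neither explanation. Nuclear copies of organelle DNA, which would draw organelle reads from both libraries, and other repeated sequence stay open as a source of the high background and were not tested, as no genome sequence is analysed here.

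The 40 summits of at least 5-fold had backgrounds of at most 17.9. Of the 18 that share a locus with another, many are summits of one region, such as 5 on chromosome 3 and 4 on chromosome 11 near 12.4 Mb, and whether the 40 lie closer together than chance was not tested. No library from untagged plants is analysed here.

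The excess of close neighbours over all regions may come from the high-background loci, since the share among the other regions, 11.6%, lay within the random range that ends at 12.2%. A small excess among the other regions is not excluded, because overlapping placements raise that range. Among regions with a −log10 q of at least 5, whether these loci account for all of the excess cannot be told apart from a remaining excess. The share among the other regions, 3.60%, lay above a random range that ends at 3.24%, as predicted if they do not, but it rested on 20 of 555 regions and did not pass after correction (permutation p = 0.03, adjusted p = 0.0599). Gene density, unmappable sequence and nuclear copies of organelle DNA stay open for both, as none was analysed here.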
